A study of Mus musculus with 16 samples.

How the data were processed

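The table holds log2 signal per probe set and array, made by the authors with robust multi-array averaging (RMA). Per the submitters' processing notes the arrays were normalized in Affymetrix Expression Console and compared in the Transcriptome Analysis Console, whose versions are not given in the sources used here. The 28846 features were read as deposited on the log2 scale, and no further normalization was applied in the fits reported first. The 6640 control features, 5222 negative and 1324 positive among them, were left out of testing, and 22206 probe sets were tested. Of these 19572 carried 1 gene symbol, 2634 carried no gene name here and 0 carried several. The 19572 stand for 19505 genes, 55 of them with several probe sets, and the probe set with the highest mean over all 16 arrays stood for such a gene in the lists. Gene names were checked against the mouse RefSeq table of assembly GRCm38.p6, used only for names, and 0 symbols had to be updated.

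All 16 arrays were fitted together with limma 3.58.1 in R 4.3.3, as a model of 4 groups with empirical Bayes variances (prior degrees of freedom 4.23, total 16.2). The comparisons were H/R against control, H/R+B12 against H/R, control+B12 against control, H/R+B12 against control+B12 and the interaction. P-values are two-sided and were adjusted over the 22206 probe sets by Benjamini and Hochberg within each comparison, with a threshold of 0.05. Fold changes are log2, with the standard error of the moderated fit and 95% intervals.

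The 28 gene lists were written down from general knowledge of each process. They were tested with camera at its preset correlation of 0.01 and again with a correlation estimated per list, and with fry, each adjusted over 28 lists. Members were also adjusted over the list alone. The mean over a list's genes was fitted per array for the intervals of mean differences. The size of the H/R response with B12 relative to that without was measured as a total least squares slope over probe sets passing in either. The other p-values are two-sided exact permutation tests over arrays. Plots were made with Python 3.11.15 and matplotlib 3.10.9.

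The genes named are the 10 largest increases and 10 largest decreases among those past the threshold, the 5 smallest p-values where none passed, up to 4 members with the smallest p-values in each list, and the injury and B12 handling genes named in any case. Predicted genes and small RNA genes were passed over. The comparisons, lists, threshold, naming rule and most alternatives were set before the data were examined. The alternatives were a block for the replicate number, fits of only the 2 groups compared, an intensity trend with robust variances, array weights, leaving out the dimmest 25% of probe sets, quantile normalization, centring on array medians, 1 probe set per gene, an unadjusted p under 0.05 with a 2-fold change, and leaving out each array. A covariate from the negative control features and leaving out the 4 arrays of lowest weight were added after seeing the data. To learn what the fit can detect, data were simulated as the H/R means plus independent noise with each probe set's spread. In these data the signal of 200 of 22206 probe sets, drawn at any level, was changed. For H/R against control the fit called 7.76% of log2 changes of 0.5, 53.1% of changes of 1 and 95.8% of changes of 2. The real comparison called 3919 probe sets, which makes its adjusted threshold less strict, so these shares do not carry over to it. In a separate simulation a slope of 0.8 was returned as 0.793. Raw array images and other data types were not used here.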

Results

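BU.MPT is a mouse proximal tubular cell line, derived from the kidney segment that reabsorbs most of the filtered load. Gene expression was measured on arrays in 4 groups of 4 samples each, 16 arrays in all. The labels give a growth temperature of 39 °C and an RNA input of 700 pg for all 16 samples. Control cells were kept in normal culture with 21% oxygen, 10% serum and 4.5 g/L glucose. H/R cells spent 3 h in about 1% oxygen without glucose or serum and then 1 h back in normal culture, a cell model of hypoxia and reperfusion. Both conditions were also run with 0.3 µM cyanocobalamin, the stable form of vitamin B12, giving the groups control+B12 and H/R+B12. The titles of all 8 treated samples read B12, but the free-text descriptions of replicates 2, 3 and 4 read B13, B14 and B15. The numbers rise with the replicate, and these samples were taken as B12. The labels do not say whether the replicates were separate cultures, so the p-values measure only the spread between these samples. The number of arrays, 4 per group, limits the precision of every value below.

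The 16 arrays were alike in overall signal. Over 22206 probe sets the array medians lay between 5.21 and 5.37 on the log2 scale, and the negative control features had medians of 5.72 to 6.23. Array medians were lower by 0.08 in the 8 H/R arrays (difference -0.079, exact permutation p = 0.000311), and the medians of the positive control features differed by -0.064 (exact permutation p = 0.0197, both two-sided). Arrays of the same group correlated at r = 0.990 to 0.994 across probe sets, and arrays differing in H/R state at r = 0.984 to 0.988. Arrays that shared the H/R state but differed in B12 correlated at 0.990 to 0.993.

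**Figure D1:**
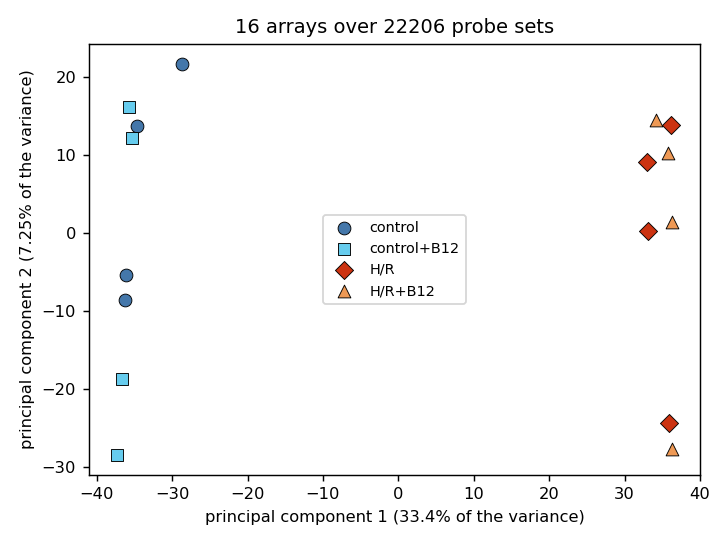
Principal components of the 16 arrays over 22206 probe sets, 1 point per array. The horizontal axis, with 33.4% of the variance, parts the 8 H/R arrays from the 8 arrays of normal culture. The B12 and no-B12 arrays overlap on both axes (vertical axis 7.25%).

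H/R without B12 raised genes of the hypoxia response, heat shock, early growth signalling, the ATF4 and integrated stress response and cholesterol synthesis. It lowered genes of mitochondrial respiration and of peroxide removal. The H/R cells also lost glucose and serum during the hypoxia and got both back afterwards. The groups cannot separate oxygen, glucose and serum, so no change is assigned to any of them alone. The largest increases after H/R were in Hspa1b, an inducible heat shock protein, with a log2 fold change of 4.35 ± 0.24 (SE, n = 4 against 4), and in Ero1a, an oxidase of the endoplasmic reticulum and a target of the hypoxia-inducible factor HIF, with 4.12 ± 0.16. The death receptor Fas rose by 4.09 ± 0.20 and the stress transcription factor Atf3 by 3.64 ± 0.20. The largest decrease was in Arrdc3, an arrestin-related adaptor, which fell by 2.46 ± 0.16 on the log2 scale.

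The other genes with the largest increases were Hspa1a (3.84 ± 0.26), Plcxd3 (3.84 ± 0.22), the mitochondrial folate enzyme Mthfd2 (3.58), the phosphatase Dusp8 (3.37 ± 0.39), Fosl1 of the AP-1 family (3.36 ± 0.23) and Srf, the serum response factor (3.24 ± 0.24). Hspa1a and Hspa1b are near-identical gene copies, so their separate values are uncertain. After Arrdc3, the genes with the largest decreases were Mpnd (-2.37 ± 0.24), the phospholipase Plch1 (-2.34 ± 0.15), Tram1 of the secretory translocon (-2.16 ± 0.12), Ccn5 (-2.11 ± 0.25) and Tlr1, a receptor of innate immunity (-2.10 ± 0.29). The centromere gene Cenpm fell to -2.05 ± 0.21, followed by Trnp1 (-1.98 ± 0.23), the transcription factor Sim1 (-1.97 ± 0.20) and the angiotensin precursor Agt (-1.92 ± 0.22). Adjusted p-values of these 20 genes ran from 3.07e-10 for Ero1a to 6.97e-05 for Tlr1. The mean signal of Plcxd3 and Dusp8 in control, and of Tlr1 and Ccn5 in H/R, lay below 5.72, the lowest negative control median, so the size of their changes is uncertain. All 4 H/R arrays lay beyond all 4 control arrays in each of the 20 genes, which were picked for their size, and in 4642 of 22206 probe sets, where chance would give 2.86% or 634.

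**Figure D2:**
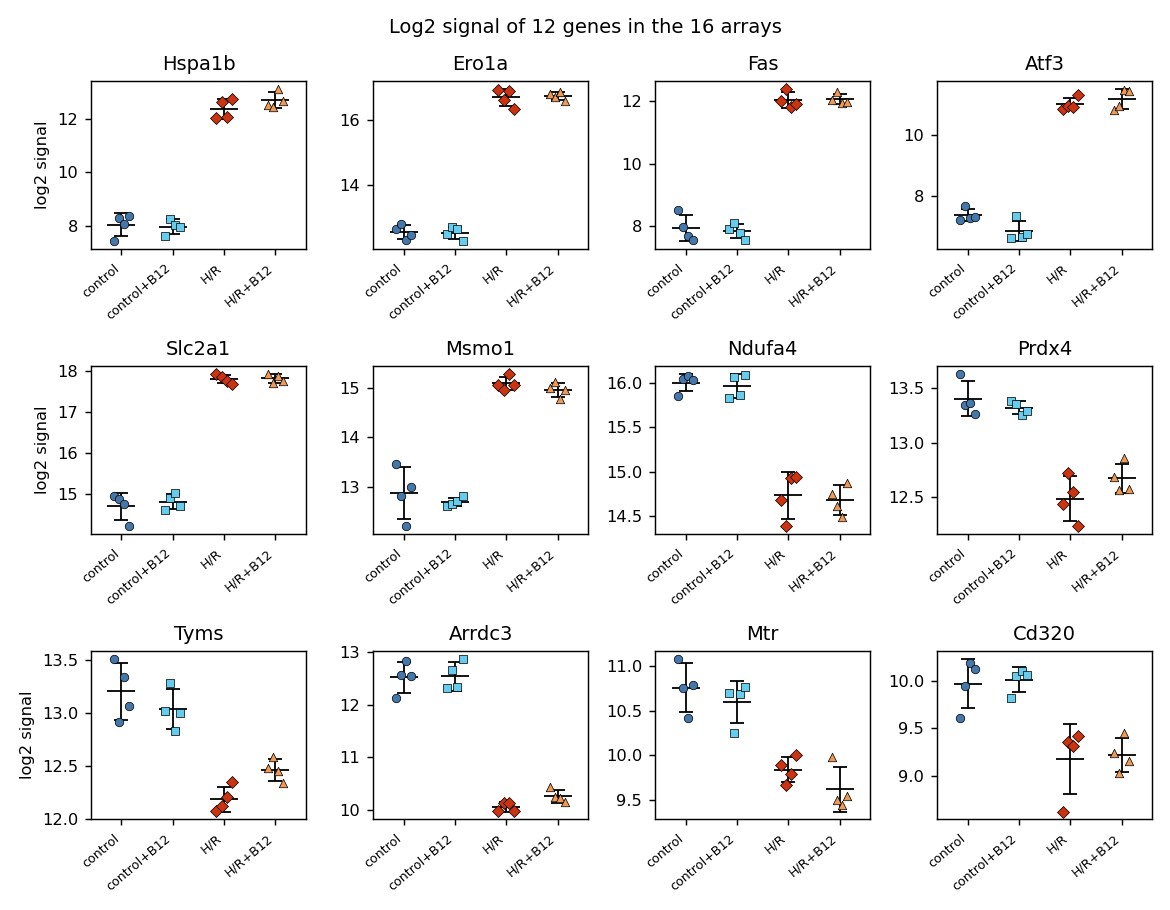
Log2 signal of 12 genes in the 16 arrays, 1 panel per gene, with points for arrays and bars for the group mean ± SD (n = 4). Hspa1b, Ero1a, Fas, Atf3, Slc2a1 and Msmo1 were higher in both H/R groups, and Ndufa4, Prdx4, Tyms, Arrdc3, Mtr and Cd320 were lower. The H/R and H/R+B12 panels overlap for 11 of the 12 genes and are apart for Arrdc3 (0.21 ± 0.16, not past the threshold).

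Of 31 measured HIF target genes 20 rose and 0 fell after H/R (22 and 0 adjusted over the list alone), with a median log2 change of 0.95 (camera adjusted p = 2.16e-20). P4ha2, a collagen prolyl hydroxylase subunit, rose by 2.69 ± 0.13, the glucose transporter Slc2a1 by 3.12 ± 0.16 and hexokinase Hk2 by 2.72 ± 0.18. The glycolysis enzymes were higher as a list but 3 of 15 rose and 1 fell (3 and 1 adjusted over the list alone; median 0.20, adjusted p = 0.0352). Pfkp was at 0.84 ± 0.15 and the lactate dehydrogenase subunit Ldhb at -0.68 ± 0.14. The glycolysis call was lost with an estimated correlation (adjusted p = 0.25 with an estimated correlation), without control 1 (0.0532) and without H/R 3 (0.075), and after quantile normalization (0.0684).

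The immediate early genes, which respond within minutes to growth factors and stress, had 22 of 36 members higher and 1 lower (26 and 1 adjusted over the list alone; median 1.13, adjusted p = 5.73e-15). Maff rose by 3.21 ± 0.21, beside Atf3, Fosl1 and Srf. Of 28 genes of the ATF4 and integrated stress response 18 rose and 2 fell (19 and 2 adjusted over the list alone; median 0.80, adjusted p = 5.36e-12). They included the amino acid transporter Slc7a5 (2.93 ± 0.22), asparagine synthetase Asns (1.75 ± 0.14) and Atf4 itself (1.61 ± 0.15). Of 17 cytosolic heat shock genes 10 rose and 0 fell (11 and 0 adjusted over the list alone; median 0.63, adjusted p = 3.68e-10), with the small heat shock protein Hspb1 at 2.46 ± 0.17 and the co-chaperone Dnajb1 at 1.30 ± 0.12.

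Cholesterol synthesis genes rose in 15 of 19 cases and fell in 1 (17 and 1 adjusted over the list alone; median 1.22, adjusted p = 7.75e-15). The sterol enzymes Msmo1 (2.23 ± 0.20), Cyp51 (1.75 ± 0.17) and Hsd17b7 (1.80) led the list, with the sterol sensor partner Insig1 at 1.26 ± 0.13. Of 28 ribosome biogenesis genes 14 rose and 0 fell (16 and 0 adjusted over the list alone; median 0.52, adjusted p = 3.68e-10), among them Tsr1 (1.51 ± 0.14), Rrs1 (1.54 ± 0.25) and the helicase Ddx21 (0.90 ± 0.14). NF-kB target genes were higher in 13 of 34 cases and lower in 2 (14 and 2 adjusted over the list alone; median 0.25, adjusted p = 0.000137). The cytokine Lif rose by 2.53 ± 0.15, the NF-kB cofactor Bcl3 by 2.85 ± 0.21, the chemokine Cxcl10 by 2.68 ± 0.20 and cyclooxygenase Ptgs2 by 1.79 ± 0.26.

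Tubule injury and dedifferentiation markers had 9 of 23 members higher and 1 lower (10 and 2 adjusted over the list alone; median 0.23, adjusted p = 0.00178). The TWEAK receptor Tnfrsf12a rose by 2.02 ± 0.14, keratin Krt19 by 2.70 ± 0.34 and Anxa2 by 0.98 ± 0.14. Krt19 lay below the negative control medians in control, so the size of its rise is uncertain. The widely used injury markers Havcr1 (0.03 ± 0.23) and Lcn2 (0.20 ± 0.13) did not pass the test. Havcr1 was near the level of the dimmest probe sets and Lcn2 was among the brightest. The injury list was not called with an estimated correlation (adjusted p = 0.115 with an estimated correlation). The p53 target genes went both ways, with 6 of 24 higher and 5 lower (6 and 5 adjusted over the list alone; median 0.19, adjusted p = 0.0399). Beside Fas, the cell cycle inhibitor Cdkn1a rose by 1.63 ± 0.12 and the death receptor Tnfrsf10b by 1.21 ± 0.18. The p53 call was lost with an estimated correlation (adjusted p = 0.0807 with an estimated correlation), and without control 2 (0.0682), control 4 (0.0574), H/R 2 (0.0689) or H/R 3 (0.0537), or with the dimmest 25% of probe sets left out (0.0609).

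Oxidative phosphorylation subunits, the parts of the mitochondrial respiratory chain and ATP synthase, fell in 24 of 37 cases and rose in 0 (29 and 0 adjusted over the list alone; median -0.51, adjusted p = 1.51e-12). Examples are Ndufa4 (-1.27 ± 0.15) and Cox6c (-0.88 ± 0.12) of the chain, and Atp5d (-0.96 ± 0.13) of the synthase. Of 22 superoxide and peroxide enzymes 11 fell and 0 rose (13 and 0 adjusted over the list alone; median -0.60, adjusted p = 0.000213). Peroxiredoxin Prdx4 was at -0.91, superoxide dismutase Sod1 at -0.65 ± 0.13 and glutathione peroxidase Gpx4 at -0.83 ± 0.17. Fatty acid oxidation and PPAR target genes fell in 7 of 23 cases and rose in 0 (8 and 0 adjusted over the list alone; 4 lower in centred arrays; median -0.28, adjusted p = 0.00888), with Acadm at -0.89 ± 0.15, Acot2 at -0.66 ± 0.15 and Hadhb at -0.58 ± 0.14.

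Endoplasmic reticulum chaperones and genes of the unfolded protein response fell in 8 of 18 cases and rose in 2 (9 and 2 adjusted over the list alone; median -0.33, adjusted p = 0.0117). The chaperone component Sdf2l1 was at -1.57 ± 0.19, Dnajc3 at -1.01 ± 0.17 and calreticulin Calr at -0.62, while Herpud1, a gene of protein disposal, was at 1.21 ± 0.17. That call was lost with an estimated correlation (adjusted p = 0.173 with an estimated correlation). S phase genes fell in 10 of 28 cases (13 adjusted over the list alone; median -0.35, adjusted p = 0.000137) and G2 and M phase genes in 8 of 27 (8 adjusted over the list alone; median -0.41, adjusted p = 6.98e-05), and 0 rose in either list. Thymidylate synthase Tyms (-1.02 ± 0.15), cyclin Ccne1 (-1.56 ± 0.24), Cenpa (-1.04 ± 0.15), Cenpe (-0.96 ± 0.16) and Kif20a (-1.09 ± 0.20) were examples. With arrays centred on their medians 7 S phase genes and 3 G2 and M phase genes were lower. Both cell cycle calls were lost with an estimated correlation (adjusted p = 0.097 and adjusted p = 0.363 with an estimated correlation). The array control 1 had the highest mean over the 55 genes of both lists, 11.87 against 11.24 to 11.42 in the other control arrays, and the H/R arrays had 11.00 to 11.08.

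The NRF2, interferon, FoxO, YAP and autophagy lists had members on both sides and were not called by camera. Fry, which tests a list on its own and not against the other genes, called the interferon (lower, adjusted p = 0.0142), FoxO (higher, 0.00281) and YAP (higher, 0.0254) lists. The p-values below are those of camera. NRF2 target genes had 3 of 22 higher and 7 lower (3 and 7 adjusted over the list alone; adjusted p = 0.602), with heme oxygenase Hmox1 (1.35 ± 0.15), cystine transporter Slc7a11 (2.05 ± 0.28, uncertain since its mean in control, 5.75, lay below the negative control medians of the 4 control arrays, though not below 5.72) and Sqstm1 (1.01 ± 0.12) up and Pgd (-0.97 ± 0.16) down. Interferon-stimulated genes had 3 of 31 higher and 8 lower (6 and 9 adjusted over the list alone; adjusted p = 0.366), with 5 lower in centred arrays and 5 higher after quantile normalization, and with Ifit3 at -1.55 ± 0.16, Ifit2 at -1.14 ± 0.15 and the peptide transporter Tap1 at 0.98 ± 0.16. FoxO and starvation genes had 10 of 25 higher and 4 lower (10 and 6 adjusted over the list alone; adjusted p = 0.13), with Errfi1 at 1.90 ± 0.17, Foxo3 at 1.35 ± 0.21 and Sesn1 at -1.01 ± 0.17. Their median was -0.08 while their mean, 0.19, and the direction of the test were positive. YAP and SRF target genes had 4 of 19 higher and 3 lower (5 and 4 adjusted over the list alone; adjusted p = 0.325), among them Ankrd1 (1.58 ± 0.16), tissue factor F3 (2.39 ± 0.25) and Amotl2 (-1.23 ± 0.16). Autophagy and lysosome genes had 3 of 28 higher and 5 lower (3 and 7 adjusted over the list alone; adjusted p = 0.636), with the lysosomal enzyme Hexa at -1.15 ± 0.14.

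The genes of cobalamin and 1-carbon metabolism, to which vitamin B12 belongs, had 4 of 33 members higher and 14 lower (5 and 15 adjusted over the list alone; median -0.44). With centred arrays 9 were lower. Camera gave adjusted p = 0.0626 and fry adjusted p = 0.000495. The camera test passed without control 1 (0.0379), without H/R 3 (0.0466) or without H/R 4 (0.0424). Methionine synthase Mtr, which uses B12 as its cofactor, fell by 0.92 ± 0.17 (adjusted p = 0.00108), and the receptor Cd320, which takes up B12 bound to its carrier, fell by 0.80 ± 0.18 (adjusted p = 0.00536). In both genes all 4 H/R arrays lay below all 4 control arrays. Methylmalonyl-CoA mutase Mmut was at -0.47 ± 0.13 (adjusted p = 0.022). Its call was lost without control 2 (0.0505), without control 4 (0.0711), without H/R 1 (0.0677), when arrays were centred on their medians (0.0556) and when only the 2 groups were fitted (0.0577). The carrier Tcn2 was at -0.22 (adjusted p = 0.441), and without control 1 at -0.42 (adjusted p = 0.0315). The B12 uptake genes Cubn (0.06 ± 0.27), Amn (0.42 ± 0.30) and Lrp2 (0.52 ± 0.23) did not pass and were near the level of the dimmest probe sets. The rises in this list included the folate enzymes Mthfd2 and Mthfd1l (1.58 ± 0.18).

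Markers of cell types were called neither by camera nor by fry after H/R. Of 27 proximal tubule markers 22 had a mean signal over all 16 arrays below the median of all probe sets. Among the 27, 1 rose (the bicarbonate transporter Slc4a4, 2.22 ± 0.21) and 2 fell (the water channel Aqp1, -0.79, and Mme, -0.52 ± 0.11; adjusted p = 0.769 for the list). Distal nephron and collecting duct markers had 1 of 20 lower, Scnn1a at -1.15 ± 0.29 (adjusted p = 0.636 for the list), and fibroblast and pericyte markers had 0 of 16 in either direction by limma (adjusted p = 0.769). Endothelial markers had 1 of 14 higher (Flt1) and 1 lower (Ehd3, -0.97 ± 0.24), leukocyte markers 1 of 17 higher (Cd14, 0.80 ± 0.13) and 1 lower (C1qb), and podocyte markers 1 of 8 higher (Foxd2, 0.86 ± 0.22; adjusted p = 0.636, 0.636 and 0.366). Ehd3, Flt1, C1qb and Foxd2 lay below the negative control medians in both groups, so their values are uncertain. Flt1, at 0.96 ± 0.28, did not pass without control 3 (0.0705), control 4 (0.0709), H/R 1 (0.0627), H/R 3 (0.0538) or H/R 4 (0.0715). C1qb, at -0.83 ± 0.25, did not pass without control 1 (0.0929), control 2 (0.0804), control 4 (0.0777), H/R 2 (0.1) or H/R 4 (0.0657), and it failed when only the 2 groups were fitted (0.0858), as did Foxd2 (0.0537). Fibroblast (median -0.03, mean 0.02) and leukocyte markers (-0.10, 0.04) had negative medians but positive means and tests. Counts adjusted over the list alone were the same for each of these 6 marker lists.

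**Figure D3:**
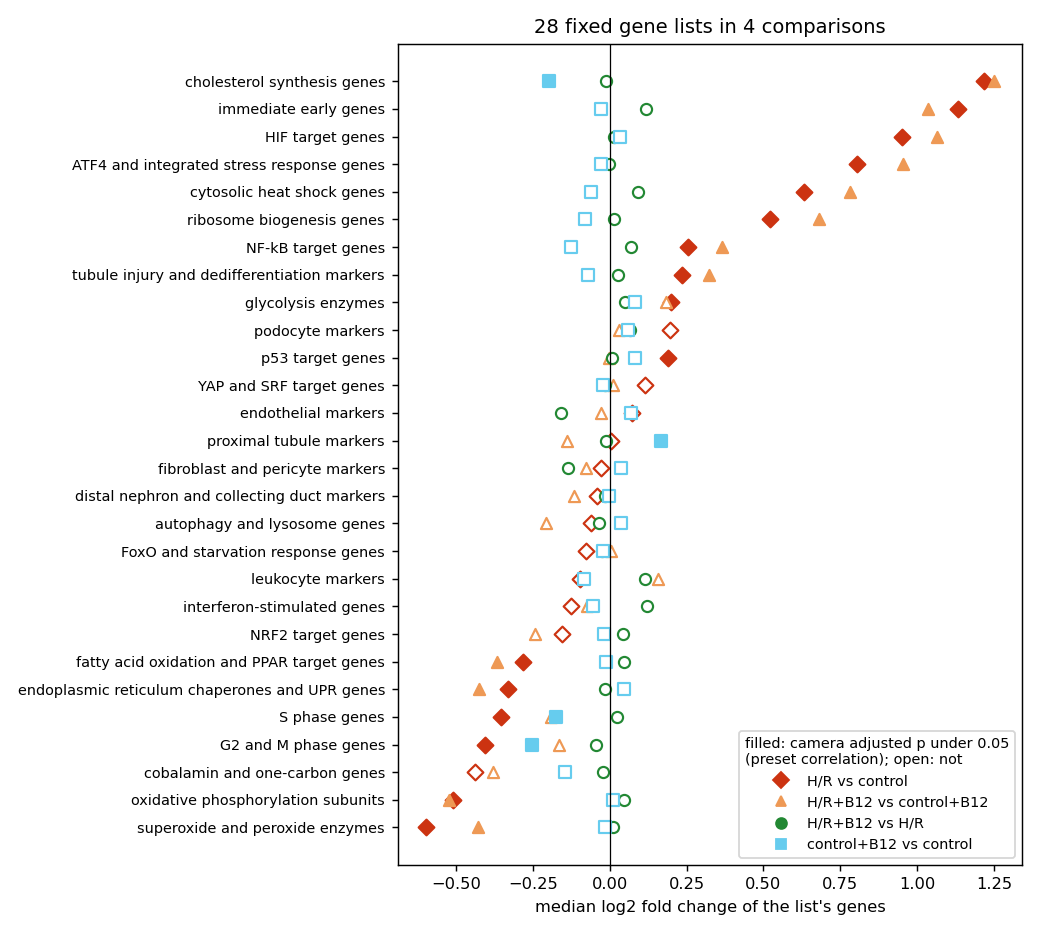
Median log2 fold change of 28 gene lists fixed in advance in 4 comparisons, with filled symbols for camera adjusted p under 0.05 at the preset correlation. Cholesterol synthesis genes had the highest median after H/R (1.22 without and 1.25 with B12). The lowest were superoxide and peroxide enzymes without B12 (-0.60) and oxidative phosphorylation subunits with B12 (-0.52), and the medians of H/R+B12 against H/R lay within 0.16 of 0.

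By limma, 3919 of 22206 probe sets passed the adjusted threshold in H/R against control, 1801 higher and 2118 lower, and 1134 of them changed at least 2-fold. With arrays centred on their medians the count was 3779 with 2133 higher and 1646 lower, so the balance between higher and lower depended on the scaling. Camera called 16 of the 28 lists at the preset correlation and 10 with an estimated correlation, and fry called 20. The 10 were the HIF, immediate early, ATF4, heat shock, superoxide and peroxide, NF-kB, cholesterol, fatty acid oxidation, ribosome biogenesis and oxidative phosphorylation lists. In each of the 16 called lists the mean over the list's genes put all 4 H/R arrays on 1 side of all 4 control arrays. That follows in part from how they were picked, and the uncalled cobalamin list did so too.

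With B12 in both arms, H/R raised genes of the heat shock, hypoxia, immediate early, ATF4 and cholesterol lists and lowered those of oxidative phosphorylation and peroxide removal. The glycolysis, p53, S phase and G2 and M phase lists, called by camera without B12, were not called by camera here. That contrast does not test a difference. Mean differences without and with B12 were 0.29 and 0.29 for glycolysis and 0.35 and 0.33 for p53. Their interactions were 0.01 ± 0.08 and -0.03 ± 0.07 (SE), so no change of either response with B12 was seen. For S phase the means were -0.40 and -0.19, and for G2 and M phase -0.45 and -0.20. Their interactions, 0.21 ± 0.09 and 0.25 ± 0.18, are treated with the interaction lists below. Hspa1b rose by 4.74 ± 0.24, Hspa1a by 4.39 ± 0.26, Atf3 by 4.34, Plcxd3 by 4.26 ± 0.22, Fas by 4.22 ± 0.20 and Ero1a by 4.19 ± 0.16 between control+B12 and H/R+B12 (SE, n = 4 against 4). Unc13a (4.10 ± 0.29), Slc7a5 (3.63 ± 0.22), Fosl1 (3.60 ± 0.23) and the nitric oxide synthase Nos2 (3.55 ± 0.18) completed the 10 largest increases. The largest decreases were in Tlr1 (-2.38 ± 0.29), Arrdc3 (-2.28 ± 0.16), Trnp1 (-2.25 ± 0.23), Sdf2l1 (-2.19 ± 0.19), Fam53b (-2.07 ± 0.29), the kinase Map2k6 (-2.03 ± 0.27), the kinase Nuak2 (-1.99 ± 0.17), Sim1 (-1.97 ± 0.20), Gas1 (-1.95 ± 0.27) and the respiratory chain subunit Ndufb7 (-1.94 ± 0.17). Plcxd3 and Unc13a in control+B12, and Tlr1 in H/R+B12, lay below 5.72, and Trnp1 in H/R+B12, at 5.76, below the negative control medians of the 4 H/R+B12 arrays, so the size of their changes is uncertain.

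The HIF target genes had 20 of 31 members higher and 0 lower (21 and 0 adjusted over the list alone; median 1.06, adjusted p = 1.3e-19), with Slc2a1 at 3.01 ± 0.16. Immediate early genes had 26 of 36 higher and 0 lower (26 and 1 adjusted over the list alone; median 1.03, adjusted p = 5.61e-17). ATF4 and integrated stress genes had 20 of 28 higher and 2 lower (20 and 2 adjusted over the list alone; median 0.95), and cytosolic heat shock genes 11 of 17 higher (12 and 0 adjusted over the list alone; median 0.78), with Hspb1 at 2.92 ± 0.17. Cholesterol synthesis genes had 16 of 19 higher and 1 lower (17 and 1 adjusted over the list alone; median 1.25), including Fdft1 at 1.59 ± 0.16. Ribosome biogenesis genes had 18 of 28 higher (21 and 0 adjusted over the list alone; median 0.68), including Heatr1 at 1.28 ± 0.16. NF-kB targets had 15 of 34 higher and 2 lower (16 and 3 adjusted over the list alone; median 0.36), including Nfkb2 at 1.46 ± 0.16. Injury markers had 9 of 23 higher and 1 lower (9 and 2 adjusted over the list alone; median 0.32, adjusted p = 0.000503, lost with adjusted p = 0.0878 with an estimated correlation).

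Oxidative phosphorylation subunits had 21 of 37 lower and 0 higher with B12 (26 and 0 adjusted over the list alone; median -0.52, adjusted p = 1.89e-10), with Cox7b at -0.84 ± 0.13. Superoxide and peroxide enzymes had 7 of 22 lower (9 and 0 adjusted over the list alone; median -0.43, adjusted p = 0.00114), and Sod1, at -0.28 ± 0.13, did not pass here. The interaction passed for neither Sod1 nor any other probe set, so no difference between its 2 responses is shown. Fatty acid oxidation genes had 7 of 23 lower (9 lower and 1 higher adjusted over the list alone; median -0.37, adjusted p = 0.00462), with Etfdh at -0.57 ± 0.13. Endoplasmic reticulum chaperones had 8 of 18 lower and 2 higher (11 and 2 adjusted over the list alone; median -0.43, adjusted p = 0.00114, lost with adjusted p = 0.0878 with an estimated correlation). Mtr (-0.99 ± 0.17, adjusted p = 0.000621), Cd320 (-0.79 ± 0.18, adjusted p = 0.00532) and Mmut (-0.59 ± 0.13, adjusted p = 0.00484) were lower in all 4 H/R+B12 arrays than in all 4 control+B12 arrays. Tcn2 was at -0.55 ± 0.17 (adjusted p = 0.0273). It did not pass without control+B12 2 (0.0764), control+B12 4 (0.0536), H/R+B12 1 (0.0634), H/R+B12 2 (0.0668) or H/R+B12 3 (0.0556), or with centred arrays (0.0631).

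Camera did not call the remaining lists with B12 in both arms. Fry called 9 of them: glycolysis (adjusted p = 0.000325), p53 (5.85e-06), YAP (0.0287), FoxO (0.00532) and leukocyte genes (0.0138) as higher, and S phase (0.0261), autophagy (0.0195), cobalamin (0.0084) and proximal tubule genes (0.0261) as lower. The p-values below are those of camera. With centred arrays the lower counts were 1 for S phase, 2 for G2 and M phase, 4 for autophagy and 3 for interferon, and 4 glycolysis enzymes were higher. S phase genes had 1 of 28 higher and 3 lower (0 and 1 adjusted over the list alone; adjusted p = 0.111), and the list passed when arrays were quantile-normalized again (0.0371). G2 and M phase genes had 4 of 27 lower (3 adjusted over the list alone; adjusted p = 0.111, and 0.0404 without H/R+B12 2). Glycolysis enzymes had 2 of 15 higher and 1 lower (2 and 1 adjusted over the list alone; adjusted p = 0.0543), and passed without control 2 (0.0496), control 4 (0.0484), control+B12 3 (0.025) or H/R+B12 4 (0.0192). The p53 targets had 6 of 24 higher and 3 lower (median -0.00, mean and test positive at 0.33, adjusted p = 0.111), the cobalamin and 1-carbon genes 6 of 33 higher and 9 lower (0.162) and the NRF2 targets 4 of 22 higher and 6 lower (0.675). NRF2 targets had a median of -0.24 and a negative test against a mean of 0.04, and interferon-stimulated genes, with 6 of 31 higher and 5 lower (0.66), a median of -0.07 against a mean of 0.09 and a positive test. The YAP and SRF targets (5 of 19 higher, 4 lower), FoxO genes (9 of 25 higher, 6 lower) and autophagy genes (4 of 28 higher, 6 lower) were also not called by camera (0.343, 0.178 and 0.305). Adjusted over the list alone, the higher and lower counts of these lists were 6 and 3 for p53, 6 and 12 for cobalamin, 5 and 6 for NRF2, 7 and 5 for interferon, 5 and 5 for YAP, 10 and 7 for FoxO and 5 and 7 for autophagy. Proximal tubule markers had 1 of 27 higher and 2 lower and leukocyte markers 2 of 17 higher (Cd14, 0.86 ± 0.13, and Ptprc, 0.93 ± 0.29; 1 and 2, and 1 and 0, adjusted over the list alone; adjusted p = 0.293 and 0.207). Ptprc, below the negative control medians in both groups, did not pass without control+B12 1 (0.069), control+B12 3 (0.0891), control+B12 4 (0.0693), H/R+B12 2 (0.0637), H/R+B12 3 (0.0843) or H/R+B12 4 (0.112). The distal nephron, fibroblast, endothelial and podocyte lists had 0 called by limma, also adjusted over the list alone (adjusted p = 0.445, 0.675, 0.968 and 0.64).

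By limma 4142 probe sets passed in H/R+B12 against control+B12, 2007 higher and 2135 lower, and 1190 changed at least 2-fold. Centred arrays gave 4022, with 2417 higher and 1605 lower. Leaving out the 4 arrays of lowest weight, an alternative chosen after seeing the data, gave 2397 and left control+B12 with 2 arrays. Camera called 12 lists at the preset correlation and 10 with an estimated correlation, and fry called 21. Each of the 12 list means put all 4 H/R+B12 arrays on 1 side of all 4 control+B12 arrays, which follows in part from how they were picked. The uncalled glycolysis, p53, S phase, YAP and FoxO lists did so too.

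The sizes of the H/R response with and without B12 were compared. Among probe sets passing in either response, 1455 were called higher in both (162.8 expected if independent) and 1485 were called lower in both (203.6 expected). Another 3 were called in both in opposite directions. Without B12 only, 346 were called higher and 633 lower, and with B12 only, 552 and 650, the 3 counted among each. Of those called without B12 only, 89.9% of the higher and 92.4% of the lower had the same sign with B12. Over these 5118 probe sets the total least squares slope of the response with B12 on that without was 1.04, and 1.03 to 1.06 when each replicate number was left out, with r = 0.917 across probe sets, which are not independent replicates. The slope was 0.963 over the probe sets called without B12 and 1.10 over those called with B12, so its side of 1 depended on the choice of probe sets.

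**Figure D4:**
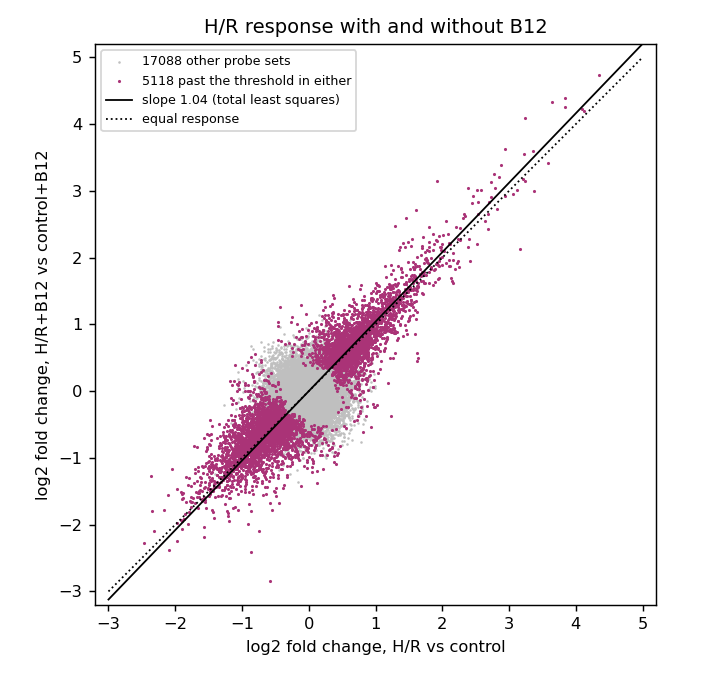
Log2 fold change of H/R against control (horizontal) and of H/R+B12 against control+B12 (vertical) for 22206 probe sets, 5118 of them past the threshold in either. The fitted line has a slope of 1.04, beside the dotted line of equal response.

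Adding B12 to cells given H/R changed no gene past the threshold. The genes with the smallest p-values were Dtd1, an editor of misloaded transfer RNA, higher in H/R+B12 than in H/R by a log2 of 0.90 ± 0.15, Nudt11 at 1.28 ± 0.23, Pstpip1 at -1.05 ± 0.20 and Meikin at 1.03 ± 0.19 (SE, n = 4 against 4; adjusted p = 0.255 each). Pnliprp2 followed at -0.85 ± 0.17 (adjusted p = 0.416). All 4 H/R+B12 arrays lay on 1 side of all 4 H/R arrays in each of these 5 genes, which follows from how they were picked. The arrays did so in 637 of 22206 probe sets, where chance would give 2.86% or 634. Meikin and Pnliprp2 in both groups, and Nudt11 in H/R, lay below the negative control medians of 5.72 to 6.23, so the size of their differences is uncertain. Nudt11 passed without H/R 1 (1.53, adjusted p = 0.0166).

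Limma called 0 of 22206 probe sets in H/R+B12 against H/R, with 1010 at an unadjusted p under 0.05 where 1110.3 would be expected by chance. The camera test called 0 of the 28 lists (smallest adjusted p = 0.141, for heat shock genes) and fry called 0 (smallest adjusted p = 0.97). Adjusted over the list alone, 0 members passed in any list. The mean difference over the HIF targets was -0.01 (95% interval -0.13 to 0.11), over the superoxide and peroxide enzymes 0.04 (-0.06 to 0.14) and over the oxidative phosphorylation subunits 0.06 (-0.06 to 0.18). Over the injury markers it was 0.00 (-0.15 to 0.16), over the cobalamin and 1-carbon genes -0.02 (-0.13 to 0.09), over the ATF4 genes 0.01 (-0.13 to 0.16) and over the heat shock genes 0.13 (-0.01 to 0.26).

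The B12 handling genes did not pass in H/R+B12 against H/R. Mtr differed by -0.22 ± 0.17, Mmut by -0.27 ± 0.13, Cd320 by 0.04 ± 0.18 and Tcn2 by -0.10 ± 0.17. Heat shock genes passed the list test without H/R 2 (0.0184) or H/R+B12 4 (0.0256), interferon-stimulated genes without H/R+B12 4 (0.0256) and oxidative phosphorylation subunits without H/R 3 (0.0139). The 95% interval of the fold change lay within 2-fold in either direction for 89.5% of probe sets and for 95.8% of the brighter 11103. These intervals bound the change in signal. The array medians, 5.21 to 5.37, lie below the negative control medians, 5.72 to 6.23. For probe sets at that level the intervals do not bound the change in RNA. Data with independent noise and 200 changed probe sets were simulated for this comparison too. There 7.16% of simulated log2 changes of 0.5 in signal, 57.3% of changes of 1 and 97.0% of changes of 2 were called. The changes were added to the signal of probe sets drawn at any level. The shares therefore do not cover RNA changes that background signal hides.

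B12 in normal culture also left every probe set under the threshold. The genes with the smallest p-values in control+B12 against control were Tmcc2 (1.00 ± 0.18), the metalloprotease gene Adam30 (-1.03 ± 0.19), Ankar (0.93), Dennd6b (0.94) and Klhl30 (-0.70), with adjusted p = 0.717 for Tmcc2 and Adam30 and 0.762 for the others (SE, n = 4 against 4). All 4 control+B12 arrays lay on 1 side of all 4 control arrays in each, which follows from how they were picked. They did so in 637 of 22206 probe sets, where chance would give 2.86% or 634. Tmcc2, Adam30, Ankar and Klhl30 in both groups, and Dennd6b in control, lay below the negative control medians, so the size of their differences is uncertain. Adam30 passed without control 2 (-1.25, adjusted p = 0.0251). Mtr (-0.16 ± 0.17), Mmut (-0.15 ± 0.13), Cd320 (0.04 ± 0.18) and Tcn2 (0.22) did not pass.

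In control+B12 cell cycle and cholesterol lists lay lower and proximal tubule markers higher at the preset correlation, with 0 single members past the limma threshold, also adjusted over the list alone. G2 and M phase genes had a median of -0.25 (adjusted p = 9.19e-07), S phase genes of -0.18 (0.000192), cholesterol synthesis genes of -0.20 (0.00985) and proximal tubule markers of 0.17 (0.0316). Their mean differences were -0.27 (95% interval -0.534 to -0.00272), -0.19 (-0.32 to -0.05), -0.18 (-0.38 to 0.01) and 0.14 (0.02 to 0.26), in the same order and not adjusted for the number of lists. Members with larger differences were Exo1 (-0.70 ± 0.21), Cdc20 (-0.55 ± 0.23) and Aurkb (-0.53 ± 0.20) of the cell cycle, Hsd17b7 (-0.55) of cholesterol synthesis and Slc27a2 (0.53 ± 0.19) and Hnf4a (0.48 ± 0.19) of the tubule, where both lie near the dimmest levels. With an estimated correlation all 4 calls were lost (adjusted p = 0.8, 0.483, 0.8 and 0.483 with an estimated correlation, in the same order), and fry called 0 lists. Without control 1, the array with the highest cell cycle mean, adjusted p-values were 0.848, 0.245, 0.885 and 0.426. The medians of the G2 and M phase, S phase and cholesterol lists were then -0.087, -0.081 and 0.002. The cholesterol call was also lost without control+B12 1 (0.11), and the proximal tubule call without control 3 (0.156), control+B12 1 (0.0785) or control+B12 2 (0.142), with the dimmest 25% of probe sets left out (median 0.01, adjusted p = 0.488) and after quantile normalization (0.0812). Ribosome biogenesis genes, at a median of -0.08, passed without control 2 (0.0205). The mean over the 55 cell cycle genes was 11.46 ± 0.29 in control and 11.23 ± 0.04 in control+B12 (SD, n = 4), a difference of -0.23 (two-sided exact permutation p = 0.0857).

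**Figure D5:**
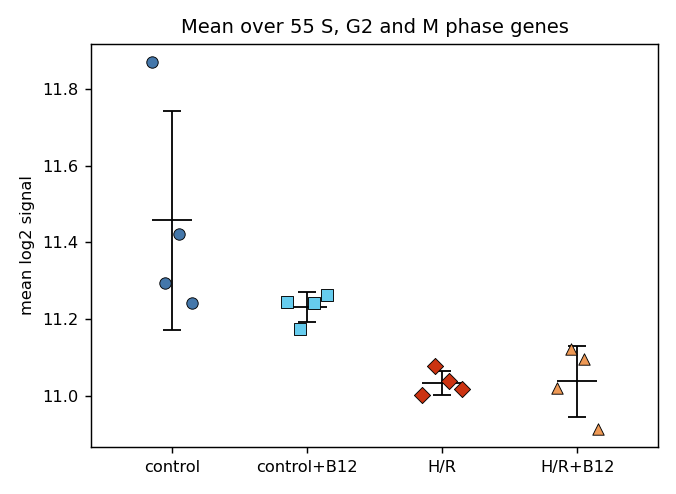
Mean log2 signal over 55 S, G2 and M phase genes, 1 point per array, with bars for the group mean ± SD (n = 4). Control 1 is at 11.87, the other control arrays at 11.24 to 11.42, and the H/R groups average 11.03 and 11.04.

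The other lists did not pass in control+B12 against control. HIF targets had a mean difference of 0.02 (95% interval -0.10 to 0.14), immediate early genes of -0.05 (-0.20 to 0.10), oxidative phosphorylation subunits of 0.00 (-0.12 to 0.13) and cobalamin and 1-carbon genes of -0.08 (-0.19 to 0.02). Among leukocyte markers 1 gene, the complement gene C1qb (-0.93 ± 0.25, adjusted p = 0.762 over all probe sets, with a signal below the negative control medians), was lower when adjusted over the list alone. Limma called 0 of 22206 probe sets and 1280 had an unadjusted p under 0.05, with 1110.3 expected. The 95% interval lay within 2-fold for 88.2% of probe sets and for 94.9% of the brighter 11103. As above, these intervals bound the signal, and not the RNA of probe sets near background. The effects of B12 in the 2 conditions correlated at r = 0.0188 across probe sets and at 0.0595 in the brighter 11103, with the same sign in 50.2% and 50.7% of them.

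Whether B12 acted differently after H/R was tested as the interaction of both treatments. No gene passed, and the smallest p-values were those of Mfsd5 (1.37 ± 0.26), Dtd1 (1.07), Cercam (-1.12), Adam30 (1.23) and the exosome subunit Exosc9 (0.74), where a positive value means a higher effect of B12 after H/R (SE, n = 4 in each of 4 groups; adjusted p = 0.803 each). Cercam and Adam30 lay below the negative control medians in all 4 groups, so the size of their values is uncertain. Limma called 0 probe sets, with 1071 at an unadjusted p under 0.05 and 1110.3 expected, and the median half-width of the 95% interval was 0.656. Among the lists adjusted over the list alone 0 members passed.

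Camera put 4 lists higher in the interaction at the preset correlation. They were S phase genes (median 0.19, adjusted p = 0.00223), G2 and M phase genes (0.23, 0.00223), cytosolic heat shock genes (0.14, 0.0391) and interferon-stimulated genes (0.15, 0.0391). All 4 calls were lost with an estimated correlation (adjusted p = 0.566, 0.721, 0.721 and 0.554 with an estimated correlation), and fry called 0. Without control 1 the adjusted p-values were 0.134, 0.751, 0.204 and 0.134. The G2 and M phase call was also lost without H/R+B12 2 (0.0526). The heat shock call was lost without control 3 (0.115), control+B12 2 (0.126), H/R 1 (0.178), H/R+B12 2 (0.172) or H/R+B12 3 (0.0633). The interferon call was lost without control 3 (0.115), control+B12 2 (0.126), H/R 1 (0.0886), H/R 2 (0.0564), H/R+B12 1 (0.0778), H/R+B12 2 (0.0702) or H/R+B12 3 (0.0642), and both were lost after quantile normalization (0.0675 and 0.0754). Cholesterol genes, at 0.0865, passed without control 2 (0.0126), control 3 (0.00991), control+B12 3 (0.0385) or H/R 3 (0.0375). Immediate early genes (0.131) passed without control+B12 3 (0.0269), H/R 3 (0.0375) or H/R+B12 1 (0.0468), and NF-kB targets (0.093) without H/R 3 (0.0414) or H/R+B12 1 (0.0258). Ribosome biogenesis genes passed without control 2 (0.0466), oxidative phosphorylation subunits without H/R 3 (0.0414), and proximal tubule markers, lower, without control 4 (0.0216), control+B12 3 (0.0476) or H/R 3 (0.0414).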

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

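The patterns weighed here came from the results, and the tests of oxidative phosphorylation against signal level and gene length were chosen only after the result was seen. The tests for the other patterns were set before their outcomes were known.

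Oxidative phosphorylation subunits fell after H/R, with a median of -0.51. Bright probe sets might fall together, but 0% of 10000 random lists matched on level had a median as low (median -0.01, lowest -0.44), which argues against it. Short genes might fall together, but 0.02% of 10000 lists matched on level and length were as low (median -0.08, lowest -0.54), which argues against length alone. The 54 cytosolic ribosomal protein genes had a median of 0.03 ± 0.011, so not every short and bright family fell. They were shorter and brighter than the list (median gene length 3310.5 against 7510, median level 15.7 against 12.9). As 1 family that is not matched to the list, they cannot decide the question. Transcript decay and synthesis were not measured.

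Cell cycle genes lay lower in control+B12 than in control, by -0.23 on the mean of 55 genes. Chance among genes that move together fits, with a two-sided exact permutation p = 0.0857 (n = 4 against 4). A single array may set the shift, since without control 1 the difference was -0.089. Array background was left open, with a difference of -0.20 ± 0.097 after the covariate from negative control features. An effect of B12 itself also stays open.

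By limma 0 probe sets passed for B12 after H/R, with 1010 at an unadjusted p under 0.05. An effect hidden by array background was tested with the covariate from negative control features, with which 0 passed, and an effect hidden by noisy arrays was tested without the 4 arrays of lowest weight, where 0 passed. Fewer than 10 had been set as evidence against both, and that bound was wrong. With all arrays 7.16% of simulated log2 changes of 0.5 in signal, 57.3% of changes of 1 and 97.0% of changes of 2 were called. A count of 0 therefore speaks against many signal changes of 2 but not against small ones. It does not speak against RNA changes in probe sets near background, which cannot be measured well. For small changes both explanations stay open, as does an absent effect of B12.

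Each comparison was repeated with the arrays relabelled. Of the 35 splits of 8 arrays, 1 (the real one) gave as many genes as H/R against control (3919, highest other 1), and 1 as many as H/R+B12 against control+B12 (4142, highest other 1). Every other split mixes arrays of both conditions, so a strong H/R effect widens the spread within its groups. Low counts in those splits therefore follow from the design. For B12 after H/R 15 of 35 splits gave at least the real 1010 probe sets at an unadjusted p under 0.05 (highest other 1396), and for B12 in normal culture 12 of 35 gave at least 1280 (highest other 1775). For the interaction 54 of 100 random assignments of B12 gave at least 1071 (highest other 1779), and for the slope 16 of 100 lay as far from 1 as 1.04 (highest other 1.06).

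Single arrays standing apart from the other 3 of their group were looked for in 147 genes and 6 array measures, 612 groups of 4 in all. Chance alone picks about 1 in 20 groups, 30.6 here, and 36 were picked. The values are the gap to the nearest array over the range of the group. Control 1 stood apart in 8 groups: Tlr1 0.832, Slc7a5 0.863, Cyp51 0.895, Ifit3 0.854, Tcn2 0.903, Ptprc 0.838, Meikin 0.857 and the median of the negative control features 0.854. Control 3 did in Bcl3 0.832, Foxd2 0.898 and C1qb 0.838, and control 4 in Etfdh 0.831. Control+B12 1 did in Dnajc3 0.830 and Cd320 0.834, control+B12 2 in Mpnd 0.884, Sod1 0.920, Mtr 0.843 and the 75th percentile of the array 0.917, control+B12 3 in Hspa1a 0.911 and Kif20a 0.971, and control+B12 4 in Hadhb 0.881.

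Among the H/R arrays, H/R 1 stood apart in Cenpe 0.896, Cd320 0.864 and Havcr1 0.963, H/R 2 in Slc7a11 0.850 and Usp54 0.856, and H/R 3 in Atf4 0.924. H/R+B12 1 did in Hspb1 0.867, Dnajb1 0.931, Cxcl10 0.855 and Aqp1 0.943, H/R+B12 3 in Amn 0.979, and H/R+B12 4 in Ldhb 0.833, Mthfd1l 0.864, Scnn1a 0.893 and Fdft1 0.831.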

How the results depend on the processing

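The H/R counts kept their size under most choices. For H/R against control, where 3919 passed, a block for the replicate number gave 3673, an intensity trend with robust variances 4517, array weights 4079, leaving out the dimmest 25% 4297, quantile normalization 3823, 1 probe set per gene 3695 and fitting only the 2 groups 3357. For H/R+B12 against control+B12, where 4142 passed, the same choices gave 3932, 4725, 4096, 4512, 4124, 3840 and 3411. Leaving out 1 array gave 3315 (without H/R 3) to 3930 (without control+B12 2), and 3528 (without H/R+B12 3) to 4148.

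The count fell to 2397 for H/R+B12 against control+B12 without the 4 arrays of lowest weight, an alternative chosen after seeing the data. That choice leaves control+B12 with 2 arrays, and the cause was not tested. The covariate from the negative control features, also added later, gave 3705 and 3833.

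For both B12 comparisons each of these fits called 0, and so did those run for the interaction, where fitting only 2 groups does not apply. Leaving out 1 array gave 0 to 1 in H/R+B12 against H/R (Nudt11) and 0 to 1 in control+B12 against control (Adam30), and 0 in the interaction. An unadjusted p under 0.05 with at least a 2-fold change, without correction for the number of tests, gave 1156 and 1214 for H/R without and with B12, 20 for B12 after H/R, 19 for B12 in normal culture and 228 for the interaction. The slope of the H/R responses was 0.963 over probe sets called without B12, 1.10 over those called with it, and 1.03 to 1.06 when each replicate number was left out. Each set was chosen on 1 of the responses, and that response was the larger in it.

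The arrays put positive over negative control features with an area of 0.851 to 0.877 under the curve. The negative control medians, 5.72 to 6.23, are above the array medians, so a change in Cubn, Amn, Lrp2, Havcr1 and most cell type markers, whose signal lies below that, cannot be measured well.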

Other observations

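Gene families picked by symbol were also examined in H/R against control. Of 76 mitochondrial ribosomal protein genes 22 fell and 6 rose (median -0.25, camera adjusted p = 0.00999, lost with adjusted p = 0.334 with an estimated correlation), with Mrpl49 at -1.15 ± 0.13 and Mrps25 at -1.37 ± 0.19 (SE, n = 4 against 4). Complex I genes of the Nduf family, which share members with the oxidative phosphorylation list, fell in 27 of 46 cases (median -0.58, adjusted p = 2.92e-13, lost with adjusted p = 0.0735 with an estimated correlation), with Ndufc1 at -1.45 ± 0.14. The 54 cytosolic ribosomal protein genes had 0 past the limma threshold (median 0.03, adjusted p = 0.789). MAP kinase phosphatases and their kin of the Dusp family rose in 8 of 24 cases and fell in 1 (median 0.21, adjusted p = 0.0142, lost with adjusted p = 0.0735 with an estimated correlation), with Dusp5 at 2.73 ± 0.25 and Dusp10 at 2.26 ± 0.21. The 39 families examined, and the genes named from them, were chosen only after the data were seen, and the list p-values are adjusted over 39.

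RNA helicases of the Ddx family rose in 13 of 32 cases and fell in 4 (median 0.30, adjusted p = 0.0216, lost with adjusted p = 0.266 with an estimated correlation), with Ddx52 at 0.89 ± 0.13. Deubiquitinases of the Usp family rose in 13 of 55 and fell in 4 (median 0.14, adjusted p = 0.0216, lost with adjusted p = 0.0735 with an estimated correlation), with Usp22 at 1.42 ± 0.12 and Usp54 at 1.69 ± 0.19. Translation initiation factors of the Eif family rose in 8 of 48 and fell in 3 (median 0.13, adjusted p = 0.0216, lost with adjusted p = 0.484 with an estimated correlation), with Eif1a at 1.19 ± 0.14 and Eif2s2 at 0.84 ± 0.12. The Ddx and Eif calls were also lost without control 2 (0.0719 each) and without H/R 3 (0.0617 and 0.0669). The proteasome family Psm, with 2 higher and 10 lower (adjusted p = 0.0874), passed without control 4 (0.0289).

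With B12 in both arms the Nduf (0 higher and 25 lower, median -0.53, adjusted p = 1.41e-10), Ddx (13 and 3, 0.41, 0.000414), Usp (16 and 2, 0.15, 0.00551), Dusp (8 and 2, 0.20, 0.00886) and Eif (17 and 2, 0.27, 0.000366) families passed again. All were lost with an estimated correlation (adjusted p = 0.0866 for Nduf, 0.0702 for Ddx, Usp and Dusp, and 0.14 for Eif, each with an estimated correlation). Homeobox genes of the Hox family had 2 of 35 higher and 11 lower (median -0.32, adjusted p = 0.00886, lost with adjusted p = 0.105 with an estimated correlation), against 2 higher and 10 lower without B12 (median -0.07, adjusted p = 0.292). The difference between these responses was not tested for the family. Mitochondrial ribosomal proteins had 6 higher and 19 lower (adjusted p = 0.0776, and 0.0449 without H/R+B12 3). For B12 after H/R 0 families passed by camera.

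The cholesterol genes could have risen because cells spent 3 h without serum, which carries sterols, and Msmo1 (2.23 ± 0.20) and Insig1 (1.26 ± 0.13) are both targets of the sterol response. An arm with serum kept in the hypoxic medium would separate the loss of serum from the loss of oxygen and glucose. A series over later times of reperfusion may show whether the respiratory chain genes, at a median of -0.51 after 1 h, return.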
